A study of Mus musculus with 18 samples.

How the data were processed

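Total RNA from mouse pluripotent stem cell cultures was labelled with biotin and hybridised to Affymetrix expression arrays. The 18 arrays used here came from 6 cell lines with 3 arrays each, which the series' design text calls biological replicates. No label says whether the 3 arrays of a line came from separate thaws, passages or dishes, so p-values between lines rest on the spread between the arrays of a line. The fibroblasts named in the same design text as the source of the induced lines were not analysed here. The deposited values are probe set intensities made by the authors with RMA (background correction, quantile normalisation and summary of probes into probe sets), per the series' design text and the submitters' processing notes. The RMA version is not given in the sources used here. The intensities were on a linear scale, with array medians between 29.1 and 30.5, and were taken to log2 before any test. The number of arrays per line limits the precision of each value.

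Of 45101 probe sets, 64 control probe sets were left out. Gene symbols came from the platform annotation and were checked by gene identifier against a RefSeq gene table of the GRCm38.p6 assembly, in which 34741 of the 34945 probe sets with 1 symbol were found and 0 symbols changed. A further 932 probe sets had several symbols and 9160 had none, and neither kind was named. The 34945 probe sets represented 18193 genes, 9010 of them with several probe sets. Each gene was represented by its probe set with the highest mean over the 18 arrays. For each named gene, the direction of its other probe sets was counted, and where no more of them shared its direction than went the other way this is given beside the genes printed as called. This count took in probe sets of any level, and those near background carry little weight.

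Groups were taken from the cell line, cell type and strain in the labels. All tests were run in limma 3.58.1 (R 4.3.3) on log2 intensities, with moderated statistics and Benjamini-Hochberg adjustment over the 18193 genes. Line contrasts came from 1 model with a mean per line over all 18 arrays (12 residual degrees of freedom). The contrast of induced pluripotent (iPS) with embryonic stem (ES) lines was fitted to the 6 line means, 4 against 2, because arrays of 1 line are not independent samples of a cell type. A gene was called changed at an adjusted p under 0.05 and a log2 difference of at least 1. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and plots.

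The designs, the lists, the rule for named genes and most alternative settings were fixed before the data were examined. By that rule, the text names the 8 largest rises and the 8 largest falls per contrast among called genes with a group mean of at least 6 (log2) in the higher group and no overlap between the arrays of the groups, leaving out clone and predicted gene symbols. Fewer of these are named for the contrasts between iPS lines. The rule also takes up to 4 called members of each list, and in every contrast the measured genes of the Dlk1-Dio3 region, Pou5f1, Nanog, Sox2, Klf4, Myc and Xist. Where under 10 genes passed, the 10 with the smallest p are given as values.

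The 23 gene lists covered core pluripotency, reprogramming factors, the Dlk1-Dio3 imprinted region, other imprinted genes, X-inactivation and Y-linked genes, fibroblast (feeder) markers, primitive and visceral endoderm, primitive streak and mesoderm, neuroectoderm, trophectoderm, primed epiblast, two-cell-stage genes, germline genes, p53 targets and cell-cycle inhibitors, cholesterol synthesis, glycolysis and hypoxia, endoplasmic reticulum and amino acid stress, immediate-early genes, heat shock, interferon and MHC class I, DNA methylation and Polycomb, Hox genes, and the LIF and STAT3 response. Listed genes without a probe set of a single symbol were not analysed here, which left 4 of 6 genes of the Dlk1-Dio3 list and 7 of 21 of the two-cell-stage list. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. The same test with a correlation estimated from the residuals, and limma's fry, were alternatives. Camera asks whether a list shifts relative to all other genes. Fry asks whether its genes move one way and makes no such comparison. Within each list, adjustment over the list alone gave the same counts of called members as adjustment over all genes in the 8 line contrasts. Over the 207 list tests, the median, the mean and the test of a list differed in sign in 30, of which 0 were called.

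The steps were tested on simulated data with the real means and spreads of the 18193 genes. With 200 genes changed by a log2 of 1.5, the contrast of IP14D-1 with ESC2 recovered 100% of them with 0 false calls. In the contrast of iPS with ES lines on line means, 88% of 200 genes changed by a log2 of 2.5 were recovered with 4 false calls. Simulated unchanged groups (50 draws) gave the overlap and correlation that the array spread of shared ES arrays alone produces. Alternatives covered the probe sets, the level filter, the scaling, the limma settings, the fold minimum, the design and each replicate left out, and the closing section gives their effect.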

Results

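Gene expression was compared among 6 mouse pluripotent cell lines grown with LIF on mitomycin-treated fibroblast feeders. R1 and ESC2 were ES lines, derived from embryos. IP14D-1, IP14D-101, IP20D-3 and IP36D-3 were iPS lines, reprogrammed from somatic cells. ESC2, IP14D-1, IP20D-3 and IP36D-3 shared the strain label B6 x D2 F1, R1 was 129X1/SvJ x 129S1 F1 and IP14D-101 was B6 x 129S2 F1. The medium held either fetal serum or a serum replacement, and the labels do not say which line had which. Arrays of 1 line correlated at a mean r of 0.995 to 0.998 across genes, and genes are not independent replicates. Lines differed by a root mean square of 0.378 (R1 and IP14D-101) to 0.708 (R1 and IP20D-3) in log2, against 0.167 to 0.249 within a line. All values below are log2 intensities with SD over n = 3 arrays, or log2 differences with the standard error of limma's model, and adjusted p-values are limma's. Among the arrays' control probe sets, the ratio of 3' to 5' beta-actin signal was 1.53 ± 0.042 (SD, n = 3) in ESC2, against means of 1.12 to 1.28 in the other lines. The 18S signal was 203 to 230 in ESC2, near 178 to 540 in IP20D-3 and 161 to 242 in IP36D-3. It was lower in the other lines, at 50.5 to 60.2 in R1, 71.7 to 88.5 in IP14D-1 and 37.8 to 46.5 in IP14D-101. The actin difference moves with every contrast against ESC2, and the 18S difference with those of R1, IP14D-1 and IP14D-101. Levels under the median of an array were not shown to lie above background, so the size of a difference that starts or ends there is uncertain.

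The labels divide the lines into iPS and ES lines, and the first comparison asks how these cell types differ. No pluripotency regulator passed the test between the cell types. Pou5f1, the central pluripotency factor, had a mean of 12.53 ± 0.05 (SD over 4 lines) in iPS and 12.38 ± 0.37 (2 lines) in ES lines. Nanog differed by 0.09 ± 0.22 and Sox2 by 0.21 ± 0.20, neither past the threshold. Klf4 differed by 0.81 ± 0.35, Myc by -0.70 ± 0.53 and Xist by 0.37 ± 0.25, without a call. The transcripts of the imprinted Dlk1-Dio3 region varied widely among the iPS lines, with Meg3 at 7.93 ± 2.79 in the 4 iPS lines and 10.76 ± 0.82 in the 2 ES lines. The differences of Rian, Mirg and Dlk1 were -2.46 ± 1.14, -1.35 ± 0.85 and -0.82 ± 0.83. Arg2, the mitochondrial arginase, differed by -1.56 ± 0.21, the signalling gene Wnt3 by -1.09 ± 0.18 and Dlc1 by 1.15 ± 0.20. These were among the 10 genes with the smallest p, as were Gm20767, Hacd1, Serinc5, Slc18b1, Plk2, Sfmbt2 and Miip, and all had an adjusted p of 1. limma called 0 of 18193 genes, with 700 at an unadjusted p under 0.05.

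Among the lists, endoplasmic reticulum and amino acid stress genes (median 0.68, adjusted p = 1.87e-06) and core pluripotency genes (median 0.33, adjusted p = 5.24e-05) were shifted upward in iPS lines at the preset correlation. Primitive streak and mesoderm (adjusted p = 4.74e-06), trophectoderm (adjusted p = 2.61e-05), two-cell-stage (adjusted p = 5.38e-05) and fibroblast marker genes (adjusted p = 0.000581) were shifted downward. Line means of the stress, pluripotency and fibroblast lists did not separate the cell types. Stress genes stood at 8.59 in the iPS line IP14D-101 against 8.78 in R1, and pluripotency genes at 10.17 in IP36D-3 against 10.21 in R1. ESC2 was lowest in both lists (8.35 and 9.9). Fibroblast markers stood at 6.35 in IP14D-1 against 6.03 in R1 and 6.12 in ESC2. The mesoderm, trophectoderm and two-cell-stage means did separate the cell types, as did those of heat shock, neuroectoderm, and DNA methylation and Polycomb genes. Two-cell-stage means lay between 3.13 and 4.06, under the median of the arrays. With 4 lines against 2, some of the 23 lists may separate by chance. Over all genes, 0 members of any list were called. Adjusted over the list alone, 2 mesoderm, 1 two-cell-stage and 1 heat shock gene were lower, and 1 p53 target was higher and 1 lower. All 13 list calls of this contrast were lost with an estimated correlation, with adjusted p between 0.259 and 0.612. The count of 0 depends on the design: lines of the B6 x D2 label alone, with arrays as replicates, gave 569 genes, and fixed line means over the 18 arrays gave 303.

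**Figure D1:**
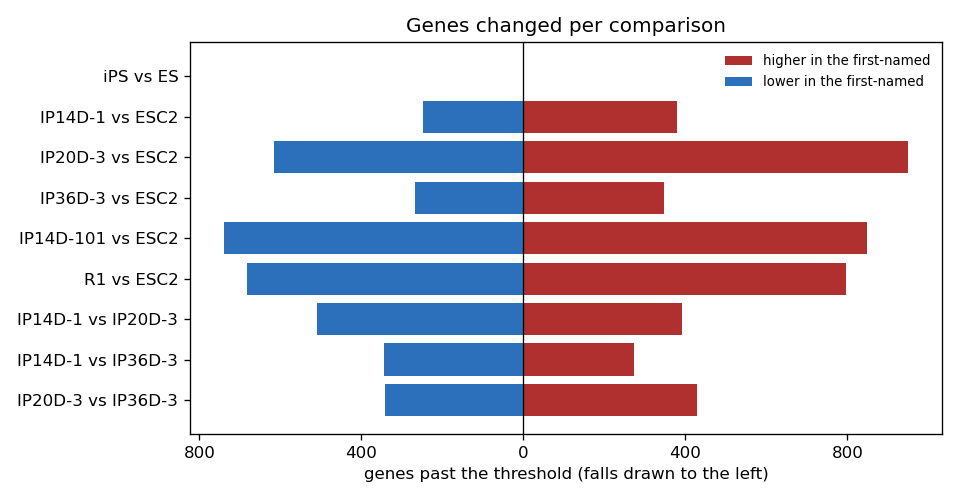
Number of genes past the threshold in each contrast (horizontal axis, genes), with genes higher in the first-named group drawn to the right and lower ones to the left. The bars run from 0 genes for iPS against ES lines to 1588 for IP14D-101 against ESC2.

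Meg3, Rian and Mirg, the maternally expressed noncoding RNAs of the Dlk1-Dio3 region, fell in IP20D-3 and IP36D-3 against ESC2 of the same strain label. Meg3 went from 11.34 ± 0.04 in ESC2 to 5.23 ± 0.11 in IP20D-3, a 69.4-fold difference, and to 5.90 ± 0.13 in IP36D-3, a 43.4-fold difference. Rian fell by 4.04 and 3.88 and Mirg by 2.38 and 2.16 in the same lines. Dlk1 differed by -0.62 ± 0.13 and -0.19 ± 0.13 there, without a call. In IP14D-1, Meg3 stood at 10.89 ± 0.08 and Rian at 7.57 ± 0.30, and neither passed the threshold, nor did Mirg with 0.48 ± 0.17. The paternally expressed Dlk1 rose in IP14D-1 by 1.35 ± 0.13, although its other probe set, with a mean under 6, did not share that direction. Of the 10 other Meg3 probe sets, 10 were lower in each of IP20D-3 and IP36D-3. As a list, the region was lower with the preset correlation (adjusted p = 8.75e-05 in IP20D-3 and 1.00e-05 in IP36D-3) and with an estimated one (adjusted p = 0.0119 and 0.00824). Fibroblast markers were lower in the same 2 contrasts, with 12 and 10 of 31 members lower, among them Lox at 3.93 ± 0.13 and 4.25 ± 0.15 against 6.81 ± 0.44 in ESC2 (adjusted p = 2.23e-06 and 7.44e-08, and 0.0631 and 0.0505 with an estimated correlation). IP14D-101 also had 10 of 31 lower, while Meg3 stood at 9.71 there.

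**Figure D2:**
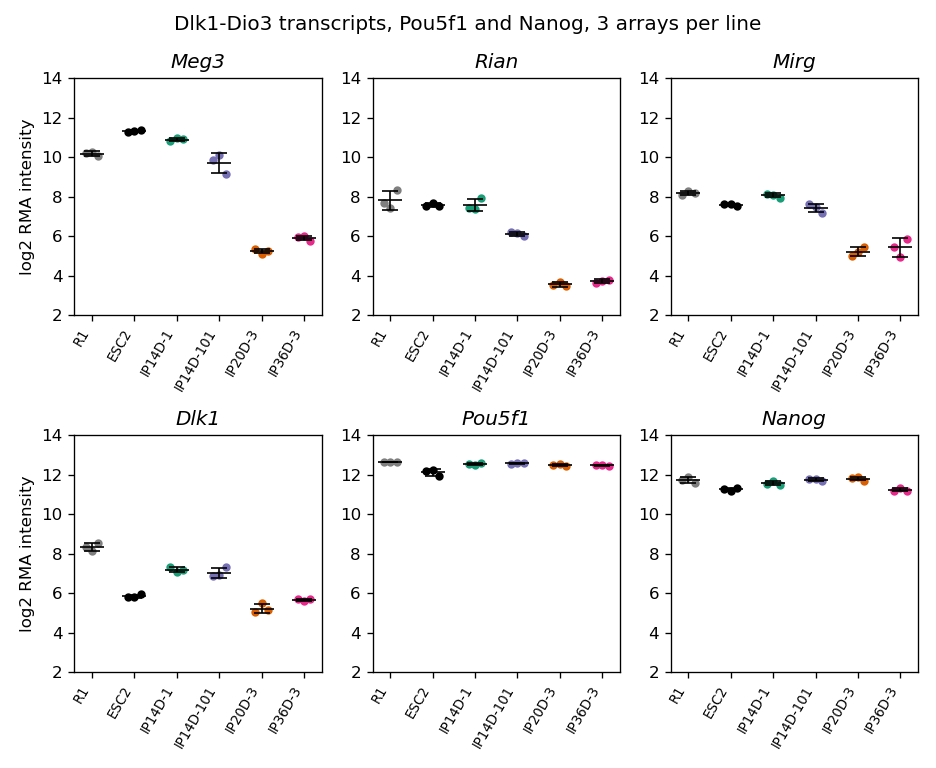
Log2 RMA intensity (vertical axis) of 4 Dlk1-Dio3 genes, Pou5f1 and Nanog in each of the 6 lines, with a point per array and a bar for the mean and SD (n = 3). Meg3 lies at 5.23 in IP20D-3 and 5.90 in IP36D-3 and between 9.71 and 11.34 in the other lines.

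In IP14D-1 against ESC2, 626 genes changed, 378 higher and 248 lower. Stress and amino acid genes led the rises: Chac1, a glutathione-degrading enzyme induced by stress, rose 40.6-fold (10.97 ± 0.34 against 5.63 ± 0.04), and the transcription factor Ddit3 rose 8.75-fold. Of 19 stress genes 13 rose and 1 fell (adjusted p = 5.1e-09, and 0.202 with an estimated correlation). Enzymes of cholesterol synthesis fell, with 6 of 20 lower, including Idi1 by 1.62, Fdft1 by 1.54 (in 1 of its 3 other probe sets too) and Hmgcs1 by 1.42 (adjusted p = 1.7e-10, and 0.0898 with an estimated correlation). Of 33 pluripotency genes 9 rose, among them Klf5 by 2.06 ± 0.08 (with 1 of its 2 other probe sets), Esrrb by 1.97 ± 0.10 and Klf2 by 1.92 ± 0.09 (adjusted p = 0.00225, and 0.0777 with an estimated correlation). For both Fdft1 and Klf5, the other probe set that shared the direction was the only one with a mean of at least 6. The inducible chaperone Hspa1b fell by 2.66, and 3 of 12 heat shock genes were lower (adjusted p = 0.00225, and 0.181 with an estimated correlation). Zfp57, a guardian of imprinting marks, rose 5.45-fold and the imprinted Peg10 stood at 6.02 ± 0.10 against 3.85 ± 0.15. Nupr1, Anp32a, Jdp2, Pck2 and Stc2 were the other rises among the 8 largest (2.44 to 3.81), and Rab26os, Gpsm1, Pwwp3b, Mfap3l, Lpar4, Atp10a and Irgm1 the other falls (-2.67 to -1.89). Klf4 rose by 1.25 ± 0.07, while Pou5f1 (0.43), Nanog (0.31), Sox2 (0.16), Myc (-0.77) and Xist (0.54) were not called. Fibroblast markers gave 2 higher of 31 (adjusted p = 0.174). Centring all arrays on the median difference, an alternative chosen after seeing the data, turned the split to 300 higher and 302 lower, and equal array medians gave 274 and 342.

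In IP20D-3 against ESC2, 1564 genes changed, 949 higher and 615 lower. Of 33 pluripotency genes 13 rose, 0 fell and 20 did not pass the threshold, with Tbx3 rising by 3.11 ± 0.11, Tcl1 by 2.70 ± 0.09, Jam2 by 2.55 ± 0.09 and Nr0b1 by 2.51 ± 0.07 (adjusted p = 1.33e-05, and 0.00988 with an estimated correlation). Genes of the primed epiblast, the later pluripotent state, fell, with 6 of 15 lower: Pou3f1 by 2.96, Fgf5 by 2.77, Sall2 by 2.43 and Otx2 by 2.17 (adjusted p = 7.91e-06, and 0.0191 with an estimated correlation). The de novo methyltransferases Dnmt3a and Dnmt3b fell by 1.67 and 1.63. Myc fell by 2.28 while Klf4 rose by 1.38 ± 0.07, and Pou5f1 (0.38), Nanog (0.54), Sox2 (0.18) and Xist (0.99) were not called. Atp12a, Zmat4 (with 1 of its 2 other probe sets), Ddit3, Catsperz, Patl2 and Aldh1l2 were among the 8 largest rises (3.39 to 4.06), and Fgfbp1, Prss23, Slc40a1, Cap1 and Rbm45 among the falls (-4.83 to -3.54). Stress genes rose, with 14 of 19 higher and 1 lower, led by Chac1 at 34.2-fold (adjusted p = 1.75e-08, and 0.119 with an estimated correlation), and Nupr1, a stress-induced nuclear protein, rose 51.1-fold. Cholesterol synthesis genes fell, with 7 of 20 lower and 1 higher (adjusted p = 2.73e-06, and 0.117 with an estimated correlation). Fibroblast markers fell, with 12 of 31 lower and 1 higher, Thbs1 by 3.38 and Acta2 by 2.73 (adjusted p = 2.23e-06, and 0.0631 with an estimated correlation). The other 2 Acta2 probe sets did not share its direction, but both had a mean under 6. Of 24 germline genes 7 rose and 1 fell: the meiotic gene Tex14 rose 7.99-fold and the X-linked Rhox5 fell by 3.64 (adjusted p = 0.00498, and 0.119 with an estimated correlation).

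In IP36D-3 against ESC2, 615 genes changed, 347 higher and 268 lower. Beyond the Dlk1-Dio3 transcripts, the protease Prss23 fell by 3.81, Rbm45 by 3.17 and the prostaglandin synthase Ptgs2 by 3.15. Tmem87a, Usp17la and Zfp229 were the other falls among the 8 largest (-2.85 to -2.70). Fibroblast markers fell, with 10 of 31 lower, Cdh11 by 2.23 (not in its other probe set) and Col5a2 by 2.22 (adjusted p = 7.44e-08, and 0.0505 with an estimated correlation). Targets of p53 and cell-cycle inhibitors fell, with 4 of 19 lower and 1 higher, Aen by 1.58 and Cdkn1a by 1.22 (adjusted p = 6.5e-07, and 0.0505 with an estimated correlation). Chac1 rose 13.8-fold and 5 of 19 stress genes were higher (adjusted p = 0.00138, and 0.476 with an estimated correlation). Core pluripotency genes moved less, with Klf5 at 1.01 ± 0.08 and Esrrb at 1.00 ± 0.10 as the 2 called of 33 (adjusted p = 0.0285, and 0.106 with an estimated correlation). Rises included Zmat4 at 5.24-fold (with 1 of its 2 other probe sets in that direction), Tmem267 at 4.02-fold and Amhr2 at 3.61-fold, with Nupr1, Catsperz, Klf11 and Patl2 between 1.85 and 2.40 in log2. Pou5f1 (0.36), Nanog (-0.03), Sox2 (-0.28), Klf4 (0.28), Myc (-0.42) and Xist (0.50) were not called. Centring on the median difference gave 262 higher and 326 lower, equal array medians 195 and 381, and repeated quantile normalisation 196 and 338. Genes of chromosome 8 made up 88 of the 347 rises, and without that chromosome 523 genes were called, 259 higher and 264 lower.

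Genes changed in the same direction in all 3 iPS lines of the ESC2 strain label numbered 124, with 64 higher and 60 lower. The shared rises were led by Chac1 (mean 4.74), Nupr1 (3.96), Ddit3 (2.80), Stc2 (2.34), Pck2 (2.33), an enzyme of mitochondrial gluconeogenesis, and Trib3 (2.24), of which Chac1, Ddit3 and Trib3 belong to the stress list. The pluripotency genes Esrrb (mean 1.70) and Klf5 (1.60) were among them, and Plk2, Magel2 and Hoxb1 among the shared falls, Plk2 without its other probe set in IP36D-3. Esrrb, Klf5, Chac1 and Pck2 were also called higher in the ES line R1 against ESC2, by 1.33, 1.72, 2.02 and 1.42. Nupr1, Ddit3, Stc2 and Trib3 were not called there. The mean of the core pluripotency list was lowest in ESC2 (9.9), against 10.17 (IP36D-3) to 10.73 (IP20D-3) in the other lines. The 3 contrasts of these iPS lines used the same ESC2 arrays: unchanged simulated groups gave 0 shared genes, and independent lists of these sizes would share 0.5. The simulated lines differed by the spread between arrays alone. Neither figure therefore covers a trait of ESC2 itself, which all 3 contrasts would share. The correlations between the contrasts were 0.59, 0.47 and 0.66 against 0.50 in simulation, and the covariances 0.147, 0.083 and 0.165 against 0.007. The 3 ESC2 arrays are too few to split, so an effect of those shared arrays cannot be separated from the rest. Of the 124 genes, 60 were also called in the same direction in the ES line R1 against ESC2, 89 in IP14D-101 and 57 in both. Genes at or above the median level alone gave 52 higher and 30 lower. Centring on the median difference gave 50 higher and 72 lower, equal array medians 40 and 89, repeated quantile normalisation 41 and 76, array weights 60 and 61, and leaving out chromosome 8 58 and 59.

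**Figure D3:**
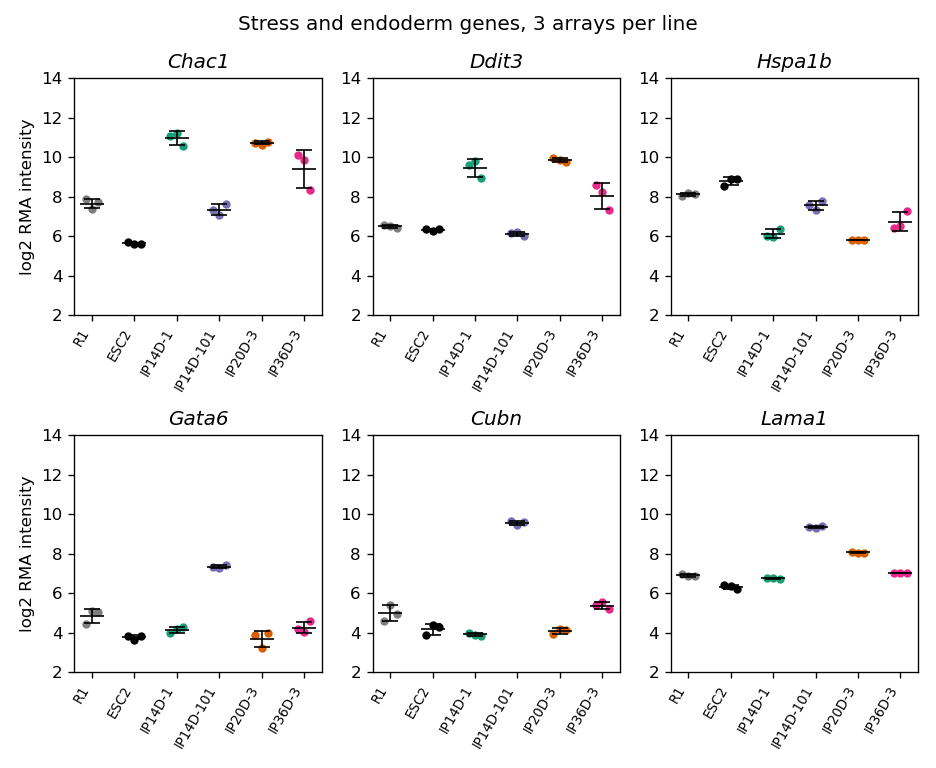
Log2 RMA intensity (vertical axis) of 3 stress genes and 3 endoderm genes in each of the 6 lines, with a point per array and a bar for the mean and SD (n = 3). Chac1 lies between 9.42 and 10.97 in IP14D-1, IP20D-3 and IP36D-3 and at 5.63 in ESC2, and Cubn lies at 9.56 in IP14D-101.

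In IP14D-101 against ESC2, 1588 genes changed, 849 higher and 739 lower, and strain and line change together in this contrast. Genes of the primitive and visceral endoderm rose, with 12 of 23 higher and 0 lower: the endocytic receptor Cubn (9.56 ± 0.12 against 4.17 ± 0.28), the transcription factor Gata6 (7.34 ± 0.07 against 3.76 ± 0.10), the laminin Lama1 8.17-fold and the adaptor Dab2 7.49-fold (adjusted p = 4.98e-06, and 0.0401 with an estimated correlation). Pluripotency genes rose at the same time, with 14 of 33 higher and 0 lower, Esrrb by 2.19 ± 0.10 and Zfp42 by 1.90 ± 0.07 (adjusted p = 0.00158, and 0.0401 with an estimated correlation). Of 15 LIF and STAT3 response genes 7 rose, among them Junb by 1.57 ± 0.12 and Tfcp2l1 by 1.51 ± 0.09 (adjusted p = 0.00158, and 0.0401 with an estimated correlation). Glycolysis and hypoxia genes rose, with 5 of 23 higher, Pfkl by 2.35 ± 0.09 with 1 of its 2 other probe sets in that direction (adjusted p = 0.00156, and 0.265 with an estimated correlation). Fibroblast markers fell, with 10 of 31 lower and 1 higher (adjusted p = 0.000302, and 0.149 with an estimated correlation). Cubn and Gata6 are under the median of the arrays in ESC2, as is Srgn, a proteoglycan core protein that stood at 9.14 ± 0.06 against 3.88 ± 0.14. Mid1 fell by 4.24, although its other 2 probe sets did not share that direction. Zfp57, Anpep and Scaf1 were the other rises among the 8 largest (2.78 to 3.32), and Lpar4, Prss23, Ptgs2, Ankrd31, Taf15, Btla and Nrk the other falls (-3.99 to -2.99). Meg3 fell by 1.64 and Rian by 1.47, Dlk1 rose by 1.18 ± 0.13 without its other probe set, and Klf4 rose by 1.38 ± 0.07. Mirg (-0.16), Pou5f1 (0.47), Nanog (0.49), Sox2 (-0.05), Myc (-0.71) and Xist (0.17) were not called. The median of all genes was shifted by 0.148, and centring on the median difference gave 605 higher and 972 lower, equal array medians 535 and 1097, and repeated quantile normalisation 681 and 872.

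The ES lines R1 and ESC2, which differ in strain, gave 1479 changed genes, 797 higher in R1 and 682 lower. They are 1 pair of ES lines and also differ in the 3' to 5' beta-actin ratio (1.12 against 1.53). The count is therefore no baseline for lines of 1 strain label. The interferon-induced GTPase Gbp2b stood at 8.98 ± 0.13 in R1 and 2.99 ± 0.17 in ESC2, Kbtbd11 at 8.12 ± 0.04 and 3.57 ± 0.15, the imprinted Peg10 at 8.08 ± 0.23 and 3.85 ± 0.15, and the integrin Itga8 at 7.33 ± 0.22 and 3.37 ± 0.17. These 4 ESC2 levels are under the median of the arrays. The neural transcription factors Olig1 and Olig2 fell by 4.68 and 4.07, and Dppa3, a maternal factor that protects imprints, fell by 2.57. Zbtb44 fell by 3.79 with its representative probe set, but its other 2 probe sets did not share the direction and 1 was called the opposite way. Fxyd6, Dpys, Mab21l4 and Itga5 were the other rises among the 8 largest (3.17 to 3.42), and Mid1, Rpgrip1, Taf15, Clmp and Ankrd31 the other falls (-4.87 to -3.38), Mid1 and Rpgrip1 with 1 further probe set each in that direction. Dlk1 rose 5.65-fold and Meg3 fell by 1.16. The size of the Meg3 fall depended on the probe set. Its other probe sets of high signal stood at 9.62, 8.85, 10.1 and 9.93 in R1 against 10.28, 9.06, 10.13 and 9.55 in ESC2. Rian (0.23, with 1 of its 3 other probe sets called lower), Mirg (0.60), Pou5f1 (0.52), Nanog (0.47), Sox2 (-0.42), Klf4 (0.51), Myc (-0.69) and Xist (0.35) were not called. Of 33 pluripotency genes 9 were higher in R1 and 2 lower (median 0.44, adjusted p = 0.448), with Klf2 at 10.52 ± 0.10 against 9.02 ± 0.06 and Klf5 higher by 1.72 ± 0.08, although its other 2 probe sets did not share that direction. Keratins of the trophectoderm list were higher, Krt19 by 1.96 ± 0.13 and Krt18 by 1.57 ± 0.16, with 4 of 18 members higher and 1 lower (adjusted p = 0.612). Cholesterol synthesis (1 higher and 2 lower of 20, adjusted p = 0.0117) and primed epiblast genes (1 higher and 4 lower of 15, adjusted p = 0.0336) were shifted downward, each with an adjusted p of 0.487 with an estimated correlation. The median of all genes was shifted by 0.149. Centring on the median difference gave 564 higher and 926 lower, equal array medians 462 and 1047, and repeated quantile normalisation 616 and 816.

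The iPS lines of 1 strain label differed from each other. Meg3 was 50.8-fold higher in IP14D-1 than in IP20D-3 and 31.8-fold higher than in IP36D-3, and all 4 Dlk1-Dio3 genes were higher in both contrasts, Dlk1 without its other probe set (adjusted p = 8.79e-06 and 1.21e-06, and 0.00689 and 0.00456 with an estimated correlation). Between IP20D-3 and IP36D-3 none of the 4 was called, and Meg3 differed by -0.68 ± 0.16 (adjusted p for the list = 0.355). Fibroblast markers were higher in IP14D-1, with 15 and 12 of 31 members higher (adjusted p = 1.32e-09 and 2.96e-10, and 0.0265 and 0.0212 with an estimated correlation). Primed epiblast genes were higher in IP14D-1 than in IP20D-3 (7 of 15, adjusted p = 1.09e-05) and lower in IP20D-3 than in IP36D-3 (7 of 15, adjusted p = 2.33e-06), with adjusted p of 0.0265 and 0.0204 with an estimated correlation. Core pluripotency genes were higher in IP20D-3 than in IP36D-3, with 10 of 33 higher and 1 lower, Tbx3 by 2.45 ± 0.11 and Jam2 by 2.54 ± 0.09 (adjusted p = 6.96e-07, and 0.00318 with an estimated correlation). Myc was 2.84-fold higher in IP14D-1 than in IP20D-3 and fell by 1.86 in IP20D-3 against IP36D-3, where Klf4 was higher by 1.10 ± 0.07. Pou5f1 differed by 0.05, 0.07 and 0.01, Nanog by -0.23, 0.33 and 0.57, Sox2 by -0.02, 0.44 and 0.46 and Xist by -0.45, 0.05 and 0.50 between IP14D-1 and IP20D-3, IP14D-1 and IP36D-3, and IP20D-3 and IP36D-3, without a call. Targets of p53 were higher in IP14D-1 than in IP36D-3, with 6 of 19 higher (adjusted p = 2.86e-09, and 0.0212 with an estimated correlation). In all, 902 genes differed between IP14D-1 and IP20D-3 (392 higher, 510 lower), 617 between IP14D-1 and IP36D-3 (273 higher, 344 lower) and 772 between IP20D-3 and IP36D-3 (429 higher, 343 lower). Repeated quantile normalisation turned the split between IP14D-1 and IP36D-3 to 344 higher and 249 lower, and that between IP14D-1 and IP20D-3 to 447 and 441. Genes of chromosome 8 made up 92 of the 344 lower in IP14D-1 than in IP36D-3, and without that chromosome the split was 270 and 252. Between IP20D-3 and IP36D-3 the split turned to 244 and 257 among genes at or above the median level, and to 2942 and 3898 without the fold minimum.

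**Figure D4:**
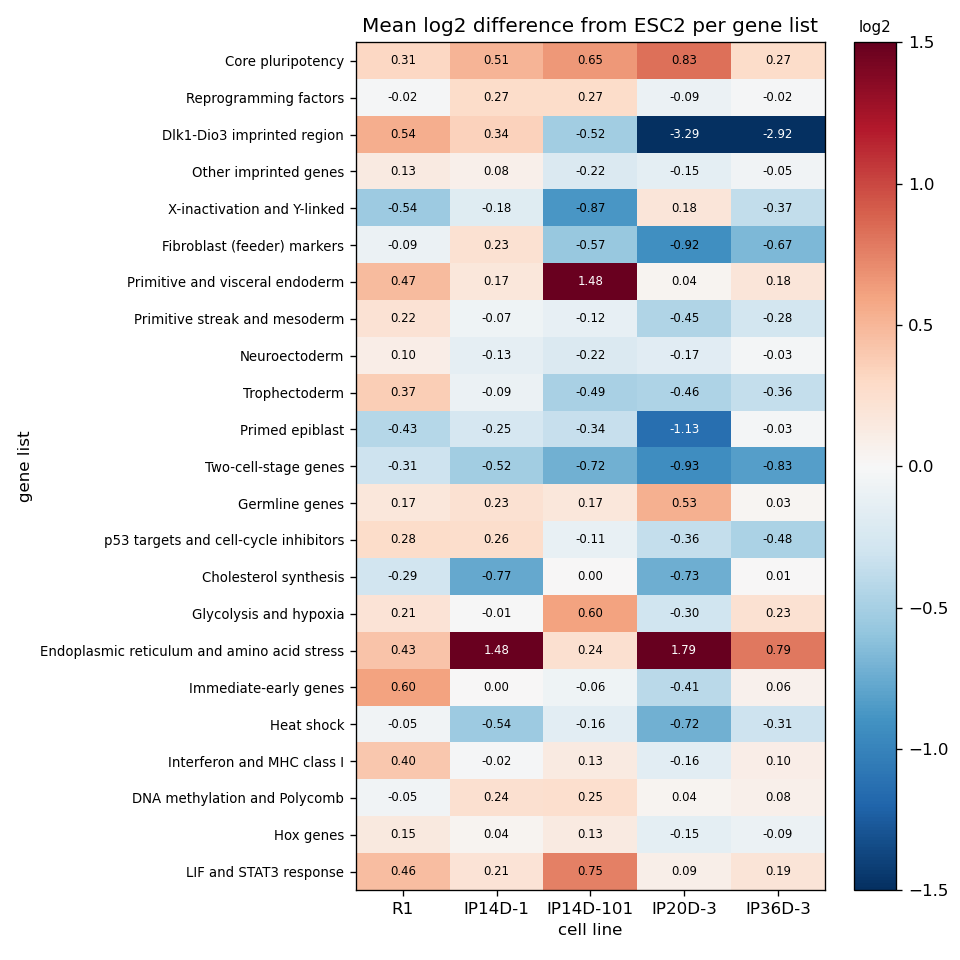
Mean log2 difference from ESC2 of each of the 23 gene lists (vertical axis) in the 5 other lines (horizontal axis), with the value printed in each cell and colours that stop at 1.5 in either direction. The Dlk1-Dio3 list lies at -3.29 in IP20D-3 and -2.92 in IP36D-3, and the endoderm list at 1.48 in IP14D-101.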

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

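The tests of explanations in this part, the splits of the samples included, were chosen after the results were seen. Results stood out here where 1 of the 4 iPS lines lay far from the others, where the same contrast differed between lines, or where probe sets outside the gene analysis changed.

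The mean of the primitive and visceral endoderm list was higher in IP14D-101 than in the other 3 iPS lines, with a gap to the nearest of 0.907 of the whole range. Each of the 3 arrays showed it, at 1.46, 1.40 and 1.58 above the ESC2 mean, which argues against 1 aberrant array (lowest value 1.4). Mature visceral endoderm cells in the culture would bring their abundant transcripts, yet the largest rise among Afp, Ttr, Apoa1 and Rbp4 was 0.42. The strain background of the line cannot be told apart from the line, since 1 line carries its strain label. Less mature endoderm cells in the culture, or expression of these genes in the stem cells themselves, may underlie the pattern, and neither was tested.

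Meg3, Rian and Mirg were low in IP20D-3 and IP36D-3. Of their 17 probe sets, 15 were lower by over 1 (log2) than in ESC2 in both lines, against a single faulty probe set. The 20 neighbouring genes, 10 on each side, had medians of 0.03 (SD 0.42) in IP20D-3 and -0.02 (SD 0.22) in IP36D-3, against the loss of a larger chromosome segment. That test is limited, since the neighbours were taken at any level and a gene near background could show no fall. Of the 42 other imprinted genes 8 were called in IP20D-3 and 5 in IP36D-3, in both directions, against 1564 and 615 of all 18193 genes. Camera did not call the list in either line (adjusted p = 0.24 and 0.37). Lines that kept Meg3 had such calls too: 6 higher and 3 lower in R1, 2 and 9 in IP14D-101, and 1 and 1 in IP14D-1. These calls therefore did not follow the low Meg3. Whether the change is one of this region alone stays open. Less RNA of feeder fibroblasts in the 2 lines was not settled by a test on R1 and IP14D-101. Of the ESC2 excess of 10 fibroblast markers over IP36D-3, IP14D-101 kept a median of 7.8% (quartiles -0.7 to 14.8) against 30.6% for Meg3, with only Vim (114.1%) above Meg3. R1, at 66.6% (15.8 to 133.9) against 43.5%, is too spread to decide. In IP14D-101, Rian (6.12 ± 0.11) and Mirg (7.43 ± 0.22) also lay above their IP36D-3 levels (3.71 ± 0.10 and 5.42 ± 0.46). The IP14D-101 values argue against feeder RNA as the explanation, but they come from 1 line of another strain label. The test on R1 and IP14D-101 replaced 2 earlier forms after their values were seen, 1 with a limit that ESC2 and IP14D-1 also stayed under and 1 on 21 low-level markers that moved little in any line (medians from -0.44 to 0.20). The Meg3 percentages come from its representative probe set alone, and in R1 the size of the fall depended on the probe set. Other Meg3 probe sets of high signal stood at 8.95, 8, 9.58 and 9.5 in IP14D-101 against 10.28, 9.06, 10.13 and 9.55 in ESC2.

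Klf4 was lower in IP36D-3 (10.12) than in the other iPS lines (11.09 to 11.22), with a gap of 0.883 of the range. The IP36D-3 level lay between those of the ES lines ESC2 (9.84) and R1 (10.35). Both flags of this kind came from 23 lists and 20 genes examined, and chance alone gives about 1 in 20.

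The effect against ESC2 differed between the iPS lines by direct contrast, with 902 genes between IP14D-1 and IP20D-3, 617 between IP14D-1 and IP36D-3 and 772 between IP20D-3 and IP36D-3. Of 10092 probe sets without a single gene symbol, 87 changed in the same direction in all 3 iPS lines of the ESC2 strain label, 14 higher and 73 lower.

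Each contrast of 2 lines has 10 splits of its 6 arrays, too few for a share under 0.05. The real values were 626, 1564, 615, 1588, 1479, 902, 617 and 772 genes, and the highest of the other splits gave 0 in each. For iPS against ES lines the real value was 0, which any split reaches. That 15 of 15 splits of the 6 lines gave as many therefore decides nothing. The highest other split gave 1. That split, R1 and IP14D-101 against the rest, had 4017 genes at an unadjusted p under 0.05 against 700 in the real one. For the genes shared by 3 iPS lines, 4 of 100 drawn splits gave at least the real 124, a share under 0.05. These splits mixed arrays of different lines, which puts line differences into the spread within groups. The share therefore cannot tell whether the real count arose by chance. The highest other gave 437, several times the real count, and what set that split apart was not tested.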

How the results depend on the processing

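The settings added after the data were examined were centring on the median difference and leaving out chromosome 8. Among the named genes and the lists, nothing called reversed direction, and other genes were not checked one by one. Over 606 pairs of named gene and contrast, 9307 values under the alternatives kept their call, 218 were weaker and 37 stronger. The iPS against ES count of 0 moved to 38 with line as a random block, 29 with the replicate block added, 303 with fixed line means and 569 with the same-strain lines only, and leaving out lines gave 0 to 1 (1 without ESC2). The designs with fixed line means and same-strain lines take the spread between arrays in place of that between lines, and the cause of the other changes was not tested. The mean of all probe sets gave 414 genes for IP14D-1 against ESC2 and 396 for IP14D-1 against IP36D-3, and the cause was not tested. Genes at or above the median level alone, which tests fewer genes, gave 501 for IP20D-3 against IP36D-3 and 82 shared genes. Without the fold minimum, which by construction admits smaller changes, the counts were 7243, 8706, 7091, 10144 and 10070 for IP14D-1, IP20D-3, IP36D-3, IP14D-101 and R1 against ESC2, 8501, 7743 and 6840 for IP14D-1 against IP20D-3, IP14D-1 against IP36D-3 and IP20D-3 against IP36D-3, and 2804 shared. Of 74 list calls, 15 were called with an estimated correlation, and fry called 144 (it makes no comparison with other genes). Leaving out 1 array at a time gave 579 to 687, 1536 to 1627, 594 to 689, 1342 to 1747 and 1423 to 1609 genes against ESC2 in the same order, 880 to 984, 593 to 702 and 737 to 818 between iPS lines, and 111 to 146 shared. Same-numbered arrays deviated together weakly at most (45 pairs, r from -0.25 to 0.26, 13 over 0.1; 13 of 18 arrays were closest to their own number, a hint from the data only), and the replicate block left the line counts at 626, 1564, 615, 1588, 1479, 902, 617, 772 and 124 and gave 62 list calls in these contrasts, 1 more than before. Signal near background limits what low genes such as Col3a1 (3.15 to 4.99 over the lines) can show.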

Other observations

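Of the tests in this part, the one along chromosome 8 was set before its result was seen, and the other 2 were chosen afterwards. Chromosome 8 was singled out after all chromosomes had been viewed.

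Of 19 interferon and MHC genes 6 were higher and 1 lower in R1 than in ESC2 (adjusted p = 0.243), H2-D1, an antigen-presenting molecule, by 2.00 ± 0.08, although 4 of its 8 other probe sets did not share the direction. Of 16 immediate-early genes 5 were higher in R1 (adjusted p = 0.061), and Junb rose 6.10-fold. The Y-linked genes Uty and Eif2s3y fell by 2.53 and 2.09 in IP14D-101 against ESC2, within a list of 5 with 2 lower (adjusted p = 0.0935). They also fell by 2.03 and 1.42 in R1 and by 1.58 and 1.27 in IP36D-3, where the other probe set of Eif2s3y did not share the direction. DNA methylation and Polycomb genes gave 2 higher and 2 lower of 27 in R1 (adjusted p = 0.132), and Tet1 fell by 1.37. Hox genes gave 1 lower of 33 in IP14D-1 (adjusted p = 0.804), neuroectoderm genes 0 higher and 2 lower of 19 (adjusted p = 0.534), and reprogramming factors 1 higher of 4 (adjusted p = 0.379). Other imprinted genes gave 2 higher and 9 lower of 42 in IP14D-101 (adjusted p = 0.0515), and Peg3 fell by 2.81 and Grb10 by 2.27 there.

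Genes of chromosome 8 were higher in IP36D-3 than in the mean of the other 5 lines, with a median of 0.37 over 500 genes, of which 81.8% were higher, against 48.1% of the genes of other chromosomes. The lowest of 10 consecutive groups along the chromosome had a median of 0.29, against a few genes or 1 segment, and in each IP36D-3 array chromosome 8 lay at least 0.25 above every other autosome, against a trend with base composition. IP20D-3 had 70 chromosome 8 genes higher and 19 lower than ESC2, where the median of that chromosome was itself low (0.06 in IP20D-3 and -0.17 in ESC2). An extra copy of chromosome 8 in most cells of IP36D-3 is a candidate explanation, since 3 copies over 2 would give 0.58 and array signals compress differences. No DNA was measured here, so this stays a hypothesis.

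The difference of R1 from ESC2 correlated across genes with that of IP14D-101 from IP14D-1 at r = 0.43, and with those of IP20D-3 and IP36D-3 from IP14D-1 at -0.22 and -0.19. Genes are not independent replicates, and the 3 pairs of iPS lines have the IP14D-1 arrays in common. The control probe sets also moved along this pattern: the 3' to 5' beta-actin ratio was 1.12 in R1 and 1.14 in IP14D-101 against 1.53 in ESC2 and 1.27 in IP14D-1. The 18S signal ran from 50.5 to 60.2 and 37.8 to 46.5 against 203 to 230 and 71.7 to 88.5 in the same order.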
